A study of Mus musculus with 4 samples.

How the data were processed

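RNA was measured by sequencing in 4 libraries of sorted mouse regulatory T cells (CD4+CD62L+CD25bright), 2 from Vav1R63W mice and 2 from Vav1R63W mice that also lack Themis1 in T cells, per the labels. The mice were C57BL/6 and 7 weeks old. Each library was assigned to its group from its title and keeps the replicate number given there, 2 or 3. The labels do not say that the replicates of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

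Reads were checked with FastQC, trimmed with Trim Galore and aligned with STAR, with MultiQC as a summary, per the submitters' processing notes and the series' design text. No versions of these tools are given in the sources used here. The design text names Ensembl release 90 for the genome and annotation, while the processing notes name the build mm9, and both are stated here because they name different mouse builds. The deposited count files hold raw read counts per gene in 3 columns, without strand and for each strand, per the file layout that STAR writes. The authors' deposited table of the whole series holds the same raw counts with the results of the authors' comparison. That table also gives a fold change as a linear ratio, a log2 fold change and p-values with their adjusted values, per the file headers. The design text names DESeq2 run through SARTools with a false discovery rate of 0.05 for that comparison. The deposited log2 fold changes need not equal unshrunken ones: Amigo2 has -1.70 in the authors' deposited table and -9.28 with DESeq2 here.

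The unstranded count column was used, because it equals the raw counts of the deposited series table for all 52636 genes in each of the 4 libraries. The named library kit does not mark strand, so reads of overlapping or antisense genes cannot be told apart, and reads shared by near-identical genes can be assigned wrongly. The 4 leading summary lines of each file (unmapped, multimapping, no feature, ambiguous) held 21.1%, 21.5%, 22.6% and 23.1% of the reads of Vav1R63W replicates 2 and 3 and the libraries labelled Themis1-deleted, replicates 2 and 3, and were left out of library sizes and tests. Gene symbols were matched by gene ID for 52403 of the 52636 IDs. Coordinates are those of GENCODE M21 (GRCm38), looked up by gene ID, and were not used for counting.

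The comparison was fitted with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr at its defaults (minimum count 10, minimum total count 15) and the robust quasi-likelihood F test of genotype, two-sided, with no block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of F. Levels are CPM, the reads of a gene per megaread of the TMM-scaled library total, and errors are standard deviations over 2 libraries. A fold against a group with 0 reads in both libraries was computed on mean CPM against a floor of 3 reads in each library. For a group with 1 to 3 reads in total, the ratio of summed counts, scaled by the TMM-scaled library totals, is given with its exact 95% binomial interval. Floors and intervals cover counting error only, not the spread between libraries, and PCR copies are not independent molecules.

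A total of 18 gene lists and 12 lists of markers of other cells were fixed from general knowledge. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. The gene lists were NF-kB target genes, the regulatory T cell signature, effector regulatory T cell and suppression genes, naive and quiescent T cell genes, immediate early and TCR-induced genes, TCR signalling machinery, cell cycle genes, inflammatory and helper T cell cytokines, interferon response genes, IL-2 and STAT5 targets, apoptosis regulators, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, cholesterol synthesis, heat shock and dissociation stress genes, and chemokine, homing and adhesion receptors. Another list was tested with them, and it and 1 named member of the cholesterol synthesis list are not reported here. The named genes are Themis, Vav1, Ptpn6 and Rela; in each direction the protein-coding genes that passed, up to 12, filled to 5 by p where fewer passed, leaving out predicted genes and immunoglobulin and T cell receptor segments; of each list the 2 members with the smallest p where none passed; and of each marker list the 2 members with the highest mean CPM. The groups, tests, lists, this rule and the alternatives that follow were chosen before the data were examined. The rule as then written left out pseudogenes, and the limit to protein-coding genes applied here is narrower. Genes named outside the rule are said to be so.

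Alternatives were DESeq2 1.42.0 at its defaults, limma-voom, DESeq2 size factors, no count filter, a minimum of 1 CPM in 2 libraries, the replicate number as a block, each library left out in turn, the strand column with more reads, a fit without robust shrinkage, a fold of at least 2 as a second threshold, and mitochondrial, ribosomal protein, immunoglobulin and T cell receptor genes left out. For the lists they were an estimated correlation and fry. Other settings, not among these and chosen after seeing the data, were a minimum mean of 100 CPM (for refits without TMM scaling), the mixed test of fry and further DESeq2 settings. Figures were drawn with matplotlib 3.10.9.

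The tests were run first on simulated counts with 50 genes changed at each fold. With the dispersions of these libraries, edgeR recovered 0%, 12%, 36% and 38% of genes changed by 2, 4, 8 and 16 fold, with 2 false calls among 9505 genes. DESeq2 recovered 4%, 32%, 54% and 68%, with 183 false calls among 10216 genes. With a dispersion of 0.02, edgeR recovered 76%, 98%, 100% and 100% with 11 false calls among 10147 genes, and DESeq2 recovered 62%, 94%, 98% and 100% with 11 false calls among 10216 genes. A list of regulatory T cell genes shifted by 1 on the log2 scale was called by camera (adjusted p = 2.69e-05) and 0 other lists of the 17 tested were. Every member was shifted alike and genes were drawn independently, so lists with correlated members were not tried.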

Results

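The series compares the transcripts of sorted regulatory T cells from Vav1R63W mice, which carry a knock-in allele of the TCR signalling adaptor Vav1, with those of Vav1R63W mice whose T cells also lack Themis1, a TCR signalling protein encoded by Themis. The title of the series places Themis1 upstream of the phosphatase SHP-1 (gene Ptpn6), Vav1 and the NF-kB subunit RelA. RNA was sequenced from 2 libraries per group, replicates 2 and 3 of each. Reads assigned to genes numbered 14003757 and 14398002 in Vav1R63W replicates 2 and 3, and 15953194 and 13963670 in the libraries labelled Themis1-deleted, replicates 2 and 3. Foxp3, the lineage transcription factor, named here outside the rule, was at 761 ± 171 CPM (SD, n = 2) in Vav1R63W cells and 881 ± 175 CPM (SD, n = 2) in the libraries labelled Themis1-deleted. Il2ra, which encodes CD25 and was also named outside the rule, was at 289 ± 19.2 and 278 ± 79.9 CPM (SD, n = 2 each).

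Themis, the targeted gene (ENSMUSG00000049109, GRCm38 chromosome 10, 28668360 to 28883818, plus strand), had 283 and 97 reads in Vav1R63W replicates 2 and 3, or 19.7 and 6.78 CPM. The library labelled Themis1-deleted, replicate 2, had 685 Themis reads (42.5 CPM), more than either Vav1R63W library, and the library labelled Themis1-deleted, replicate 3, had 0. The targeted gene therefore goes against the label of replicate 2, and each direction given below is between labels. Gene counts check the deletion only if the deleted exons carry the reads, which gene-level values do not show. The log2 fold change of Themis was 0.68 ± 2.74 (SE, edgeR adjusted p = 1.000). Without the library labelled Themis1-deleted, replicate 2, it was -10.55 (edgeR adjusted p = 0.463), a fitted value against a single library with 0 reads, and with limma-voom it was -3.05.

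Vav1 (ENSMUSG00000034116, GRCm38 chromosome 17, 57279100 to 57328031, plus strand), which carries the same knock-in allele in both groups, was at 228 ± 38.3 CPM in Vav1R63W cells and 117 ± 59.0 CPM in the libraries labelled Themis1-deleted (SD, n = 2 each). Its log2 fold change was -0.96 ± 0.44 (SE, edgeR adjusted p = 1.000). Ptpn6 (ENSMUSG00000004266), which encodes SHP-1, was at 237 ± 34.9 and 167 ± 15.0 CPM, a log2 fold change of -0.51 ± 0.22. Rela (ENSMUSG00000024927), which encodes RelA, was at 261 ± 15.1 and 185 ± 15.5 CPM, a log2 fold change of -0.50 ± 0.19. None of Vav1, Ptpn6 and Rela passed the test (edgeR adjusted p = 1.000 for each). Both libraries labelled Themis1-deleted lay below both Vav1R63W libraries for all 3. Among genes at a mean of at least 100 CPM, as these are, the groups did not overlap for 33.5%, where chance gives 33.3%. Without the library labelled Themis1-deleted, replicate 2, the log2 fold change of Vav1 was -1.60, and without replicate 3 it was -0.52.

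**Figure D1:**
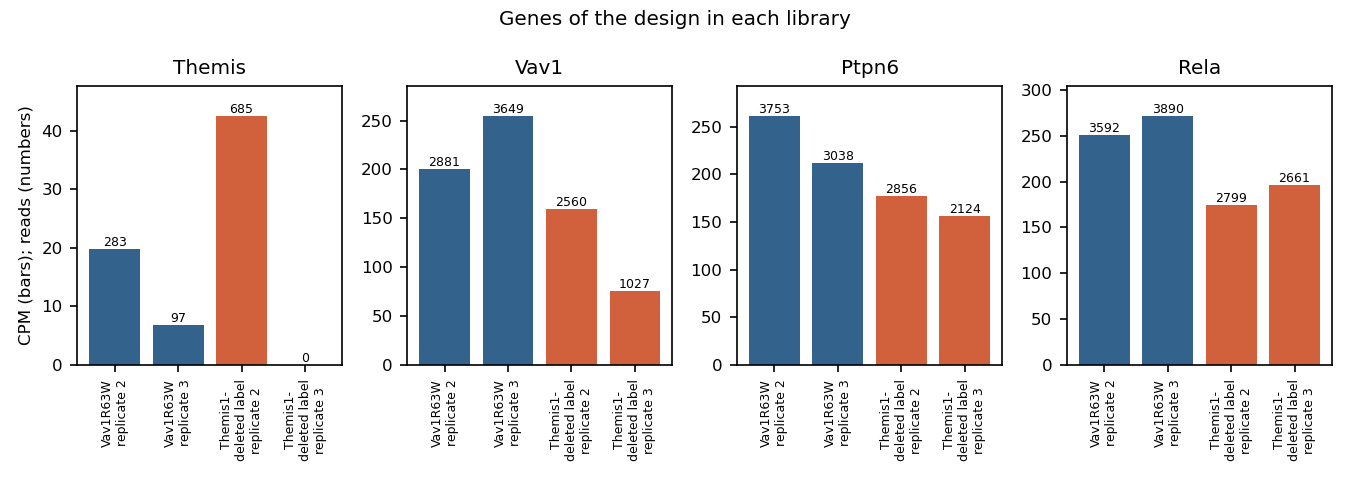
Bars show CPM of Themis, Vav1, Ptpn6 and Rela in each of the 4 libraries, with raw read counts above them, on a separate axis from 0 for each gene. Themis has 685 reads in the library labelled Themis1-deleted, replicate 2, and 0 in replicate 3, while the other 3 genes are lower in both of these libraries than in both Vav1R63W libraries.

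Across the transcriptome, leading genes were taken among the protein-coding genes kept by the rule for named genes. Those higher in the libraries labelled Themis1-deleted, by smallest p, were Ncapd3, Anapc1, Cd247, Ccr8 and Ect2. None of them passed the edgeR test. Cd247 (ENSMUSG00000005763), the CD3 zeta chain of the T cell receptor, was at 114 ± 18.4 CPM in Vav1R63W cells and 313 ± 44.7 CPM in the libraries labelled Themis1-deleted (SD, n = 2 each), a log2 fold change of 1.46 ± 0.23. Ccr8 (ENSMUSG00000042262), a chemokine receptor of effector regulatory T cells, was at 13.3 ± 0.769 and 89.9 ± 0.587 CPM, a log2 fold change of 2.76 ± 0.46. Anapc1 (ENSMUSG00000014355), a subunit of the anaphase-promoting complex, was at 42.1 ± 12.5 and 235 ± 59.3 CPM (log2 2.48 ± 0.37). Ncapd3 (ENSMUSG00000035024), a condensin II subunit, was at 4.71 ± 1.42 and 84.5 ± 7.37 CPM (log2 4.16 ± 0.60). Ect2 (ENSMUSG00000027699) had 1 and 4 reads in the Vav1R63W libraries and 478 and 581 in the libraries labelled Themis1-deleted.

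In the other direction stood Srrm2, Amigo2, Cenpo, Slc43a2 and Rbsn, which did not pass the edgeR test either. Srrm2 (ENSMUSG00000039218), a splicing factor, was at 206 ± 2.44 CPM in Vav1R63W cells and 71.9 ± 5.37 CPM in the libraries labelled Themis1-deleted (SD, n = 2 each), a log2 fold change of -1.52 ± 0.24. Cenpo (ENSMUSG00000020652), a centromere protein, had 483 and 780 reads in the Vav1R63W libraries and 0 in both others, at least 217-fold lower against the floor of 3 reads per library. Amigo2 (ENSMUSG00000048218) had 289 and 918 reads in Vav1R63W cells and 1 in each of the other libraries, a ratio of summed counts, scaled by TMM library totals, of 625 (exact 95% interval 173 to 5170). Slc43a2 (ENSMUSG00000038178), an amino acid transporter, had 214 and 1084 against 1 and 1, a scaled ratio of 673 (186 to 5560). Rbsn (ENSMUSG00000014550) had 412 and 747 against 1 and 0, a scaled ratio of 1201 (215 to 47483). These counts and ratios are of the unstranded column, and the intervals cover counting error only, not the spread between libraries. In the strand column with more reads the log2 fold change was -1.45 for Cenpo (edgeR adjusted p = 0.974), -1.36 for Slc43a2 (edgeR adjusted p = 1.000) and -6.87 for Amigo2, against fitted values of -12.33, -9.22 and -9.11 in the unstranded column. In the libraries labelled Themis1-deleted, replicates 2 and 3, Cenpo had 202 and 234 reads in the first strand column and 204 and 241 in the second, and Slc43a2 had 102 and 253, and 90 and 246. The kit does not mark strand, so the gene of origin of these reads is not known.

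**Figure D2:**
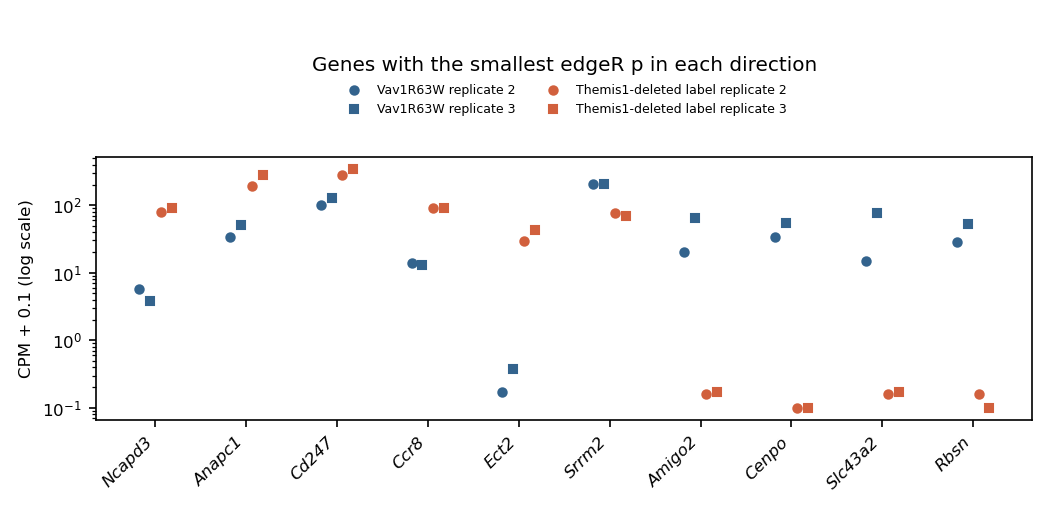
Points show CPM + 0.1 on a log scale in each library for 10 genes, 5 per direction. These had the smallest edgeR p among the protein-coding genes kept by the rule for named genes. Color marks the group and shape the replicate number. The groups do not overlap for any of the 10 genes, which were picked by p from these same libraries. Amigo2, Cenpo, Slc43a2 and Rbsn had at most 1 read in each library labelled Themis1-deleted in the unstranded column, which is drawn here. In the strand columns of these libraries Cenpo had 202 to 241 reads and Slc43a2 had 90 to 253.

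The edgeR quasi-likelihood test called 0 of 10216 genes, with 509 genes (4.98%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.900. limma-voom called 0 genes, with 438 at an unadjusted p under 0.05, and DESeq2 called 206 of 10748, 85 higher and 121 lower in the libraries labelled Themis1-deleted. With the same settings DESeq2 called 540 genes when the libraries were split by replicate number and 202 in the remaining split. All 10 genes above were among the DESeq2 calls, with adjusted p from 3.16e-07 for Ncapd3 and Cenpo to 0.00141 for Srrm2. Of the 206 DESeq2 calls, 173 had at most 10 reads in total in one of the groups, and 40 had over 3 reads in only 1 of the 4 libraries. The authors' deposited table called 123 genes, 58 higher and 65 lower, of 7865 with an adjusted p. It was made from the same counts, so shared calls and directions are not independent. DESeq2 here also called 49 of the 123, all in the same direction, and did not call the other 74. Of the 123, 22 had at most 10 reads in total in one of the groups, and 0 had over 3 reads in only 1 library. The DESeq2 count was 628 without Vav1R63W replicate 2, 414 without Vav1R63W replicate 3, 2161 without the library labelled Themis1-deleted, replicate 2, and 881 without the one labelled Themis1-deleted, replicate 3. All 10 genes above, picked by p from these same counts, were also among the calls of the authors' deposited table. Their adjusted p there ran from 1.41e-13 for Ncapd3 to 0.00890 for Slc43a2. Among 2004 genes at a mean of at least 100 CPM, the groups did not overlap for 672 (33.5%), where chance gives 33.3%.

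Of 23 tested members of the regulatory T cell signature, 0 passed, 10 had a positive and 13 a negative difference of mean log2 CPM, and the median of these differences was -0.02. Medians and signs of list members below are of the same difference, whose median over all tested genes was -0.04. Ctla4, an inhibitory receptor, was at 165 ± 5.77 CPM in Vav1R63W cells and 103 ± 10.7 CPM in the libraries labelled Themis1-deleted (SD, n = 2 each; edgeR adjusted p = 0.987). Tnfrsf9, a costimulatory receptor, was at 404 ± 47.4 and 323 ± 6.04 CPM. Effector and suppression genes had a median log2 difference of 0.36, with 19 of 26 members positive and 0 passing. Within that list Ccr8 was higher, as above, whereas Gzmb, which encodes granzyme B, had 100 and 217 reads in Vav1R63W cells and 0 and 1 in the libraries labelled Themis1-deleted. The ratio of summed counts of Gzmb, scaled as above, was 329 (exact 95% interval 58.5 to 13017). That interval covers counting error only, not the spread between libraries. Naive and quiescent T cell genes had a median of -0.06 over 20 members with 0 passing. Klf3, a Krüppel-like factor of quiescent lymphocytes, was at 112 ± 23.8 and 245 ± 10.5 CPM (log2 1.13 ± 0.25, edgeR adjusted p = 0.900), and Txk, a Tec family kinase, was at 134 ± 6.16 and 76.6 ± 43.8 CPM.

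Of the signalling lists, TCR signalling machinery held 47 tested members, 27 with a positive and 20 with a negative difference, a median log2 difference of 0.13 and 0 passing. Besides Cd247, Rasgrp1, which activates Ras in T cells, was at 89.3 ± 24.6 CPM in Vav1R63W cells and 203 ± 11.7 CPM in the libraries labelled Themis1-deleted (SD, n = 2 each; log2 1.18 ± 0.30, edgeR adjusted p = 0.900). NF-kB target genes had a median of -0.08 over 28 members with 0 passing. Traf1 was at 258 ± 3.85 and 178 ± 27.9 CPM, and Bcl3, an atypical inhibitor of NF-kB, at 65.8 ± 25.2 and 133 ± 15.4 CPM. Immediate early and TCR-induced genes had a median of 0.09 over 25 members with 0 passing. Their named members were Tnfrsf9, given above, and Per1, with 26 and 81 reads against 0 and 2, a scaled ratio of 55.4 (exact 95% interval 15.0 to 464). The intervals of Per1 and of Apaf1 below cover counting error only, not the spread between libraries. Per1 had an edgeR unadjusted p of 0.067 and a DESeq2 adjusted p of 0.666. IL-2 and STAT5 targets had a median of 0.07 over 16 members with 0 passing. Their members with the smallest p were Gzmb and Cish, a feedback inhibitor of cytokine signalling at 128 ± 12.3 and 178 ± 16.6 CPM. Apoptosis regulators had a median of -0.14 over 23 members with 0 passing. Apaf1, the apoptosome scaffold, had 144 and 402 reads against 1 and 0, a scaled ratio of 566 (101 to 22391), and Mcl1, a survival factor, was at 809 ± 15.9 and 662 ± 87.3 CPM.

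Interferon response genes had a median log2 difference of -0.22, with 21 of 30 members negative and 0 passing. Ifit3 was at 86.0 ± 2.21 CPM in Vav1R63W cells and 44.3 ± 2.66 CPM in the libraries labelled Themis1-deleted (SD, n = 2 each; log2 -0.96 ± 0.37, edgeR adjusted p = 1.000), and Ifi27l2a at 1178 ± 23.3 and 1026 ± 2.34 CPM. Only 6 of the 21 inflammatory and helper cytokine genes had enough reads to be tested, and 0 passed. Ccl5 was at 3.84 ± 3.16 and 13.6 ± 9.34 CPM. Tnf was at 4.47 ± 6.32 and 19.4 ± 23.2 CPM, and its fold change turned negative (log2 -0.56) without the library labelled Themis1-deleted, replicate 3. Chemokine, homing and adhesion receptors had a median of 0.12 over 25 members with 0 passing. Their named members were Ccr8 and Itgal, the integrin chain of LFA-1, at 290 ± 12.1 and 387 ± 11.1 CPM. Cell cycle genes had a median of -0.22 over 23 members with 0 passing, and members had fold changes of both signs. Aurkb, a mitotic kinase, had 361 and 183 reads against 0 and 0, at least 93.3-fold lower, whereas Top2a, a topoisomerase of dividing cells, had 5 and 0 against 101 and 684.

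Among metabolic and housekeeping lists, glycolysis had a median log2 difference of -0.09 over 21 members with 0 passing. Its members with the smallest p had fold changes of opposite sign. Pfkp, a phosphofructokinase, was at 102 ± 21.5 CPM in Vav1R63W cells and 210 ± 40.9 CPM in the libraries labelled Themis1-deleted (SD, n = 2 each), and Tpi1, triosephosphate isomerase, at 213 ± 9.45 and 117 ± 24.2 CPM. Oxidative phosphorylation genes had a median of 0.08 over 47 members with 0 passing, and 32 were positive. Ndufa9 and Ndufb5, subunits of complex I, were at 251 ± 9.27 and 357 ± 32.0 CPM, and at 109 ± 0.969 and 166 ± 9.54 CPM. Cytosolic ribosomal proteins had the narrowest spread, with a median of 0.10 (interquartile range 0.03 to 0.15) over 48 members, 38 positive and 0 passing. Rps27 was at 2680 ± 3.73 and 3236 ± 107 CPM (log2 0.27 ± 0.08, edgeR adjusted p = 0.900), and Rpl34 at 690 ± 20.1 and 823 ± 33.9 CPM. Cholesterol synthesis genes had a median of 0.12 over 18 members with 0 passing, with Mvd at 26.2 ± 2.46 and 57.8 ± 14.2 CPM. Heat shock and dissociation stress genes had a median of -0.09 over 16 members with 0 passing. The chaperone genes Hsp90aa1 and Dnaja1 were at 456 ± 27.7 and 310 ± 47.9 CPM, and at 519 ± 42.7 and 397 ± 1.62 CPM.

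**Figure D3:**
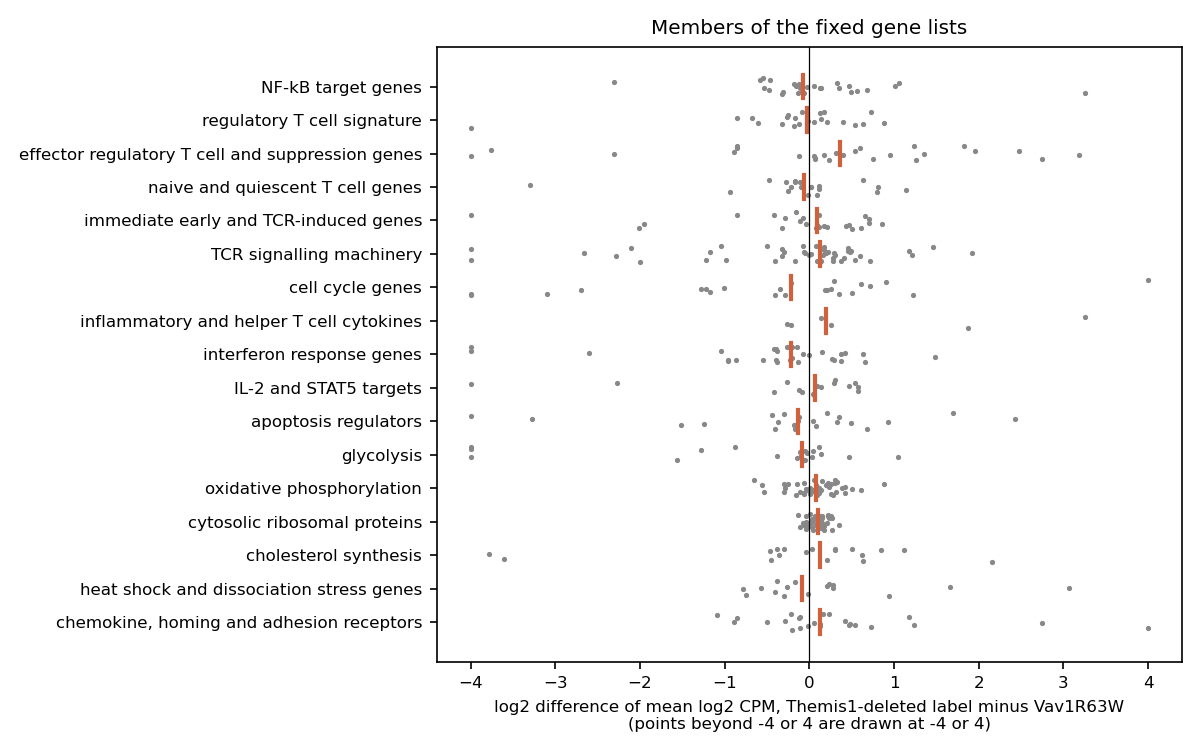
Each point is a tested member of a gene list described here, placed by the difference of its mean log2 CPM between the libraries labelled Themis1-deleted and the Vav1R63W libraries, and red bars are list medians; points beyond the axis limits are drawn at them. Medians lie between -0.22 for cell cycle and interferon response genes and 0.36 for effector and suppression genes. The median of all tested genes was -0.04, and members of every list shown lie on both sides of 0.

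camera called 0 of the 18 lists (smallest adjusted p = 0.761), 0 had an unadjusted p under 0.05, and 0 were called with an estimated correlation (smallest adjusted p = 0.975 with an estimated correlation). fry, which tests whether the genes of a list move on balance in a given direction without comparing them with other genes, called 0, with a smallest adjusted p of 0.166 for glycolysis. The mixed test of fry, which counts changes in either direction and was added after seeing the data, called 6 lists: TCR signalling machinery, cell cycle genes and IL-2 and STAT5 targets (adjusted p = 0.0257 each), glycolysis and chemokine receptors (0.0346 each) and oxidative phosphorylation (0.0454). It called 2 lists in each of the other splits of the libraries, with smallest adjusted p of 0.00383 and 0.0316. No list member passed adjusted over the list alone, 0 in total, as over all genes. Of the members of the lists described above, DESeq2 called Ccr8, Cd247, Top2a and Rps27 higher and Gzmb, Cbl, Aurkb and Apaf1 lower in the libraries labelled Themis1-deleted. The authors' deposited table called Ccr8, Cd247, Klf3 (adjusted p = 0.00106), Rasgrp1 (0.00699), Rps27 (0.00586) and Pfkp (0.0275) higher and Cbl (0.00483) and Tpi1 (0.0406) lower among these members. The median, the mean and the direction of camera differed in sign for 8 lists: NF-kB targets, the regulatory T cell signature, naive genes, immediate early genes, TCR machinery, IL-2 and STAT5 targets, cholesterol synthesis and heat shock genes.

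Of the tested markers of other cell types, 0 passed the edgeR test. Ighm, the immunoglobulin mu constant gene, was at 1084 and 1242 CPM in the Vav1R63W libraries and 1262 and 1343 CPM in the libraries labelled Themis1-deleted, and Cd79b was at 60.5 ± 4.93 and 49.8 ± 20.7 CPM (SD, n = 2 each), while 7 of the 16 B cell markers had no read in any library. Ctss and Cybb, of the monocyte and macrophage markers, were at 764 ± 65.8 and 931 ± 140 CPM and at 17.6 ± 0.861 and 8.09 ± 11.4 CPM, and 11 of 16 such markers had no read. Cst3 and Bst2, of the dendritic cell list, were at 287 ± 12.7 and 253 ± 43.5 CPM and at 162 ± 23.2 and 123 ± 14.6 CPM. Nkg7 and Gata3, listed for NK and innate lymphoid cells, were at 136 ± 27.0 and 142 ± 30.5 CPM and at 65.5 ± 37.3 and 117 ± 19.0 CPM. Cd8b1 and Prf1, for CD8 T cells, were at 32.1 ± 9.43 and 24.96 ± 7.21 CPM and at 19.7 ± 7.14 and 18.1 ± 25.5 CPM, and Cd8b1 also stood for immature thymocytes with Tcf12 at 64.4 ± 25.1 and 57.0 ± 36.4 CPM. Igfbp4 and Il7r, for conventional CD4 T cells, were at 325 ± 40.7 and 287 ± 3.81 CPM and at 109 ± 29.6 and 88.7 ± 14.5 CPM. Pecam1 and Epcam, for stromal and endothelial cells, were at 48.9 ± 9.26 and 78.1 ± 7.63 CPM and at 17.1 ± 5.95 and 4.38 ± 6.19 CPM. The members named are the highest of each list. No read in any library was found for 9 of 11 stromal and endothelial and 7 of 10 NK and innate lymphoid markers. The same held for 6 of 14 dendritic cell, 3 of 8 CD8 T cell and 5 of 10 immature thymocyte markers. The named erythroid, platelet and plasma cell markers each had reads in some libraries only, with Hba-a1 at 79 and 0 against 50 and 49 reads, Car2 at 0 and 131 against 0 and 0, Itga2b at 29 and 1 against 0 and 303, Gp9 at 0 and 0 against 0 and 99, and Derl3 at 1 and 103 against 0 and 0. Platelet markers summed to 29.6 CPM in the library labelled Themis1-deleted, replicate 3, the highest of the 4 libraries. The 11 neutrophil markers had 0 reads in all 4 libraries.

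The library labelled Themis1-deleted, replicate 3, stood apart from the other 3. It had reads for 10809 genes, against 12009, 11695 and 11940 in Vav1R63W replicates 2 and 3 and the library labelled Themis1-deleted, replicate 2, thinned to its depth, and the highest share of reads on genes annotated as ribosomal RNA outside the mitochondria, 1.31% against 0.589%, 0.741% and 0.856%. Mitochondrially encoded genes took 0.840%, 0.960%, 1.01% and 1.11% of reads in the same order, with replicate 3 of the deleted label last. The first principal component of log2 CPM (49.9% of the variance) separated this library from the rest. Across genes, which are not independent replicates, the Spearman correlation of log2 CPM was 0.850 between the Vav1R63W libraries, 0.786 between the libraries labelled Themis1-deleted, and 0.776 to 0.861 between libraries of different labels.

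Many genes were well counted in one library and near 0 in its replicate. Between the Vav1R63W libraries, 859 of 8767 genes (9.80%) with at least 100 reads in either library had at most 3 in the other, and between the libraries labelled Themis1-deleted 1349 of 8708 (15.5%) did. Pairs of different label gave 798, 895, 1271 and 1337 such genes. By level, shares were taken over all genes of the level, whether or not either library had 100 reads. They were 17.3% to 22.7% at 1 to 10 CPM, 0.314% to 2.65% at 30 to 100 CPM, and 0 in all 6 pairs at 100 CPM or more. Of the leading genes and list members called by DESeq2, Ncapd3, Ccr8, Ect2, Top2a, Cenpo, Aurkb, Gzmb, Apaf1, Cbl, Amigo2, Slc43a2 and Rbsn lie below 100 CPM in both groups, whereas Cd247, Anapc1, Srrm2 and Rps27 average above 100 CPM over the 4 libraries.

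**Figure D4:**
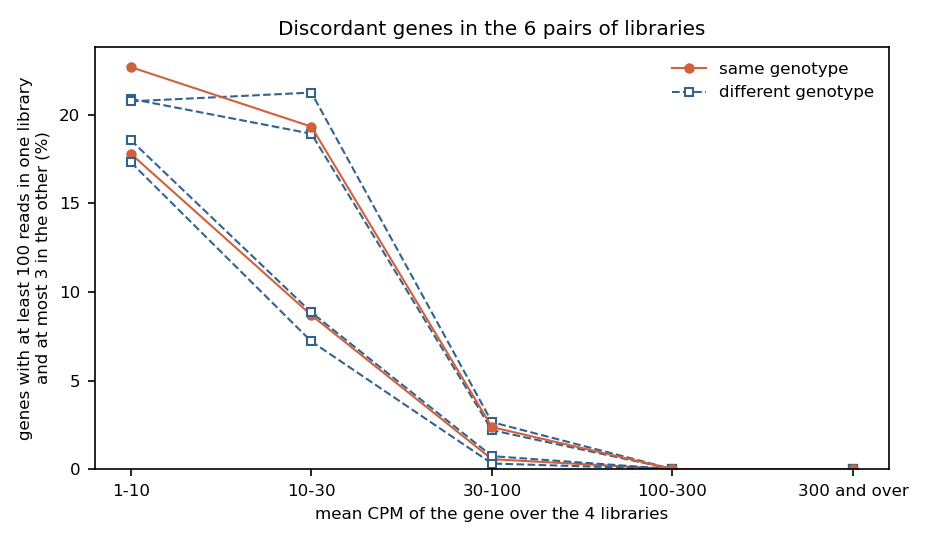
Lines show, for each of the 6 pairs of libraries, the percentage of genes with at least 100 reads in one library and at most 3 in the other, by the mean CPM of the gene over the 4 libraries; solid lines are pairs of the same genotype label and dashed lines pairs of different label. Same-label and different-label pairs overlap at each level, and all are at 0 from 100 CPM upward.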

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

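The DESeq2 settings and the limit of 100 CPM below were chosen after the results were seen. The count of genes called by edgeR was 0 under each alternative run with edgeR or limma-voom, including each library left out, and 206 with DESeq2. At a mean of at least 100 CPM (here without TMM scaling) edgeR also called 0 of 2005 genes (91 at an unadjusted p under 0.05). camera called 0 lists under each alternative, including directional fry, although up to 5 of the 18 changed direction with a library left out. The mixed test of fry, which asks for changes in either direction and was added after seeing the data, called 6 lists. Replicate numbers are shared between the groups, and the correlation across genes of the deviations of the libraries numbered 2 was 0.018. With 2 libraries per group and many discordant genes, this value cannot exclude a shared batch. The split by replicate number gave 540 DESeq2 calls, against 206 by genotype and 202 in the remaining split. With the replicate number as a block the edgeR count stayed 0 (163 at an unadjusted p under 0.05). The fold change of Themis turned from 0.68 to -2.93 with that block and to -3.05 with limma-voom. It ran from -10.55 to 1.68 with each library left out. The mean CPM of Themis was higher in the libraries labelled Themis1-deleted (21.3 against 13.3), but its difference of mean log2 CPM was -2.28. The sign thus depends on whether levels or their logs are averaged, and the cause of each move was not tested. Vav1 kept its direction under each alternative.

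The DESeq2 count of 206 became 452 with a local dispersion trend, 110 with that trend and shrunken fold changes, 5 with shrunken fold changes alone, 504 with a replicate block and 3 at a mean of at least 100 CPM, and ran from 414 to 2161 with each library left out (628 without Vav1R63W replicate 2, 414 without replicate 3, 2161 without the library labelled Themis1-deleted, replicate 2, 881 without replicate 3). The cause was not tested, except that fewer genes were tested at 100 CPM. Where a label keeps a single library, that library is assumed to vary like the other group.

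Of the other 60 named genes, all kept their direction under the alternatives that keep 4 libraries, and 16 passed with DESeq2. By over 1.5 fold, a limit set after the results were seen, 6 differed from the main fit with the replicate block (Prf1 from -0.12 to -3.12, for example), 11 with limma-voom (Prf1 to -3.10), 9 and 12 without Vav1R63W replicates 2 and 3, 12 and 11 without the libraries labelled Themis1-deleted, replicates 2 and 3, and 10 in the strand column with more reads. In that column Cenpo (log2 from -12.33 to -1.45), Slc43a2 (from -9.22 to -1.36) and Amigo2 (from -9.11 to -6.87) differed most. The causes were not tested. With each library left out the log2 fold changes that changed sign ran from -0.17 to 0.29 for Nkg7, from -0.55 to 0.0066 for Il7r, from -7.91 to 0.87 for Prf1, from -0.71 to 8.62 for Hba-a1, from -1.05 to 0.36 for Tcf12, from -0.78 to 0.085 for Cd79b, from -0.56 to 11.16 for Tnf and from -6.98 to 7.15 for Itga2b; none of these passed, and a single library decides each. The depth was 13963670 to 15953194 reads, and at 100 CPM or more no pair of libraries held a discordant gene.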

Other observations

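At a mean of at least 100 CPM, where no pair of libraries held a discordant gene, DESeq2 called 7 genes of its 206, which were named after their values were seen. Cd247, Anapc1 and Rps27 were higher in the libraries labelled Themis1-deleted, and Srrm2, Snx1, Il21r and Arpc5 were lower. Il21r, the receptor of interleukin 21, was at 488 ± 32.3 CPM in Vav1R63W cells and 268 ± 47.9 CPM in the libraries labelled Themis1-deleted (SD, n = 2 each), a DESeq2 log2 fold change of -0.86 ± 0.25 (adjusted p = 0.0415). Snx1, a sorting nexin of endosomes, was at 200 ± 4.75 and 80.4 ± 19.1 CPM, a log2 fold change of -1.31 ± 0.39 (DESeq2 adjusted p = 0.0415). When DESeq2 was fitted to genes at this level alone (CPM without TMM scaling), Cd247 (log2 1.43 ± 0.31, adjusted p = 0.00380), Anapc1 (2.45 ± 0.40, adjusted p = 2.31e-06) and Srrm2 (-1.54 ± 0.37, adjusted p = 0.0170) passed. The edgeR test called 0 at this level. DESeq2 calls at this level were not counted for the other splits of the libraries. The authors' deposited table called 51 genes at this level.

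The tests on missing transcripts and on Themis reads below were chosen only after the results were seen, and the test on chromosome 10 before. A set of 51 genes had no read in either library of one label and at least 100 in both libraries of the other, 35 absent from the libraries labelled Themis1-deleted and 16 from the Vav1R63W libraries. Of the 51, 5 had over 3 reads in the strand columns in a library of the empty label. Loss of transcripts between libraries whatever the genotype may account for such genes, since same-label pairs held 1.03 times as many discordant genes as pairs of different label (means of 1104 and 1075). The genotype stays open: the 51 genes compare with 64 when the libraries are split by replicate number, the highest other, and 3 splits are too few for a share under 0.05. DESeq2 called 206 genes between the labels and 540 and 202 in the other splits at its defaults, and 452, 540 and 404 with a local dispersion trend.

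Themis reads in a library labelled Themis1-deleted are a second pattern. A swap of libraries between the groups stays open: the lower Vav1R63W library held 97 Themis reads, fewer than a library labelled Themis1-deleted, and reads from exons outside the deleted part could remain in a swapped library. Reads from exons outside the deleted part could give the 42.5 CPM in replicate 2, and gene counts cannot place them. Chance loss of Themis in replicate 3 might give its 0 reads, since 19.3% of genes at 10 to 30 CPM were near 0 in one library labelled Themis1-deleted and well counted in the other. These cannot be told apart, and a single wrong label or cells that kept the gene stay open too.

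A hypothesis was that DNA carried along with the Themis allele changes its neighbours on chromosome 10. Within 10 Mb of Themis, DESeq2 called 3 of 50 genes against 203 of 10697 elsewhere, an odds ratio of 3.30 (exact 95% interval 0.651 to 10.4, Fisher's exact test, two-sided, p = 0.0706), which does not pass. The 3 genes, named after their values were seen, were Akap7 (0 and 0 reads against 247 and 367), Dse (1 and 0 against 141 and 414) and Perp (0 and 414 against 0 and 0). The authors' deposited table called 0 of 36 there, an odds ratio of 0 (interval 0 to 6.86, p = 1). Carried DNA and missing transcripts cannot be told apart for these genes with so few calls.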
